A study of Mus musculus with 34 samples.

How the data were processed

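The 4C libraries of 2 mouse plasmacytomas, TEPC1165 and PCT4961, were analysed, with 2 libraries of each tumor. Circular chromosome conformation capture (4C) with HindIII reports the DNA fragments that were ligated to a chosen bait fragment, here in the immunoglobulin heavy chain locus Igh. Both tumors are from Balb/c mice per the labels, which also give PCT4961 the genotype AID-/- BclXL. The series holds 34 samples, and the other 30, histone mark and RNA polymerase II profiles and 1 RNA-seq sample, were not used here.

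The authors deposited, per the file headers, read counts for 12836 consecutive windows of 200 kb of the mouse genome build mm9. A count in these deposited tables is the number of reads on the HindIII fragments of a window, and a further column counts the fragments with at least 1 read. The number of HindIII fragments per window was the same in the deposited tables of all 4 libraries. The counts were not normalized. The aligner of the 4C reads, the position of the bait and any removal of PCR copies are not given in the sources used here. Bowtie 0.12.8 is named by the submitters' processing notes for other samples of the series only.

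The bait window was taken as the highest window of chromosome 12, which was 12:114400001-114600000 in all 4 libraries. The 11 windows within 1 Mb of it (the bait region) were left out of the tests. Windows with at least 10 reads in at least 2 libraries were tested, which left 3449. The test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM factors, a prior count of 2, the tumor as the only term and Benjamini-Hochberg adjustment. It was two-sided, with a threshold of 0.05. Log2 fold changes give PCT4961 over TEPC1165, so a positive value is higher contact in PCT4961. Reads of regions fixed before the data were examined were summed and fitted with the library factors and spread of the windows, and their p-values were adjusted over the list alone. These regions were Myc-Pvt1 (15:61000001-63000000), Mycn (12:12000001-14000000), Igk (6:67000001-71000000), Igl (16:18000001-20000000) and the rest of chromosomes 15 and 12. Percentages of reads are of the reads outside the bait region, unless another base is given. Chromosome shares were compared with a two-sided exact permutation test, for which the smallest p with 2 against 2 libraries is 0.333. The labels do not say that the 2 libraries of a tumor came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Reads carried no molecular identifiers in the tables, so 95% Wilson intervals and floors of 3 counts cover counting error only.

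Named windows followed a rule fixed before the data were examined. It took every fixed region, and per direction the 10 called windows with the largest fold change in which both PCT4961 libraries lay on the same side of both TEPC1165 libraries, neighbours merged. It also took the highest window of each tumor on chromosomes 6, 12, 15 and 16 without the bait region, and the 5 highest windows of each tumor outside chromosome 12. The rule's step that names genes inside windows, and the planned comparison of gene groups (plasma cell, B cell, T cell and myeloid genes and the neighbours of Myc and Mycn), need gene positions in mm9 and were void. The gene table used here is of GRCm38 and served only for names and the order of neighbouring genes.

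Runs of raised contact were the consecutive windows around an anchor in which both libraries of one tumor had more reads than both of the other. The anchors were the highest PCT4961 window outside chromosome 12 and the highest on chromosome 12 more than 10 Mb from the bait. The run anchored on TEPC1165 was added after the data were seen. Decay was the mean RPM (reads scaled to the library total) per window in distance bands on each side of the bait, with the bait window counted in the lower band within 1 Mb; that band was also computed without it, and all bands with each library left out, both added after the data were seen. Agreement of libraries was the Pearson correlation of log2(reads + 1) across windows, which are not independent replicates.

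Alternatives planned before the data were examined were total-read and DESeq2 (1.42.0) scaling, DESeq2 as the test, a replicate block, other filters and prior counts, windows outside chromosome 12 alone, other rules for shares, runs and decay, and leaving out each library. Detected fragments in place of reads, reads corrected for the estimated sharing between same-numbered libraries, and bins of 1 Mb were added afterwards. The edgeR script was tested on simulated counts. With 10% of the estimated spread it called 100% of 34 windows changed 64-fold with a mean of at least 1000 reads and 5 of 3137 unchanged windows. With the full estimated spread it called 0 of 26 such windows and 0 of 2271 unchanged ones. Descriptive values were computed with Python 3.11.15, pandas 2.3.3 and scipy 1.17.1.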

Results

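Contacts of the Igh locus were measured by 4C in the plasmacytomas TEPC1165 and PCT4961, tumors of antibody-secreting cells, with 2 libraries per tumor. The comparison asks which sequences each tumor's Igh locus contacts and how far along the partner chromosome the contact reaches. The PCT4961 libraries held 1668589 and 2178689 reads and the TEPC1165 libraries 1890718 and 1776498. Outside the bait region lay 62.8% and 62.7% of the PCT4961 reads and 91.8% and 88.4% of the TEPC1165 reads. Reads fell on few fragments: 11226 and 10685 of the 823057 HindIII fragments were detected in PCT4961, and 10295 and 9191 in TEPC1165. The 10 highest windows of a library held 29.5% to 55.7% of its reads.

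The Igh bait of TEPC1165 contacted the Myc-Pvt1 region of chromosome 15 far more than that of PCT4961. Myc encodes a growth-promoting transcription factor, and Pvt1 is its non-coding neighbour. The region took 29.4% ± 7.35 of the reads in TEPC1165 and 1.79% ± 0.0291 in PCT4961 (SD, n = 2 each). The log2 fold change was −3.83 (SE 0.32, edgeR adjusted p = 8.35e-10 over the list alone), and the log2 ratio of read shares was −3.74 between the libraries numbered 1 and −4.29 between those numbered 2. The log2 fold change of the region ran from −4.37 to −2.47 when a library was left out. Of its 7 tested windows 5 were lower in PCT4961 over all windows tested. The highest window of both tumors outside chromosome 12 was 15:61800001-62000000, with 282973 and 382973 reads in TEPC1165 and 12510 and 16799 in PCT4961 (log2 fold change −3.85, SE 0.26, edgeR adjusted p = 3.73e-09). Nearly as many of its 69 fragments were detected in PCT4961 (55 and 58) as in TEPC1165 (57 and 60). Across the region the PCT4961 reads were 4.53% and 4.46% of the TEPC1165 reads in the library of the same number. The estimated reads shared with the same-numbered library (4.95% and 4.98% of the TEPC1165 reads) exceeded the PCT4961 reads of the region, so the size of the fold change depends on that estimate and no corrected fold is given.

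The Igh bait of PCT4961 contacted the Mycn region, near the other end of chromosome 12, far more than that of TEPC1165. Mycn encodes a transcription factor of the same family as Myc. The region took 26.4% ± 1.37 of the reads in PCT4961 and 0.359% ± 0.000879 in TEPC1165 (SD, n = 2 each), a log2 fold change of 6.44 (SE 0.36, edgeR adjusted p = 1.35e-12 over the list alone). The log2 ratio of read shares was 6.14 between the libraries numbered 1 and 6.25 between those numbered 2. Of its 7 tested windows 6 were higher in PCT4961. Window 12:12800001-13000000 was the highest PCT4961 window of the chromosome outside the bait region, with 170587 and 237211 reads against 4908 and 4077 in TEPC1165 (log2 fold change 6.19, SE 0.28, edgeR adjusted p = 2.94e-12). Over the region the TEPC1165 reads were 2.34% and 1.51% of the PCT4961 reads in the library of the same number. After subtraction of the estimated shared reads, window by window and not below 0, 1826 and 507 TEPC1165 reads were left and the log2 fold change was 8.42, which depends on that estimate.

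**Figure D1:**
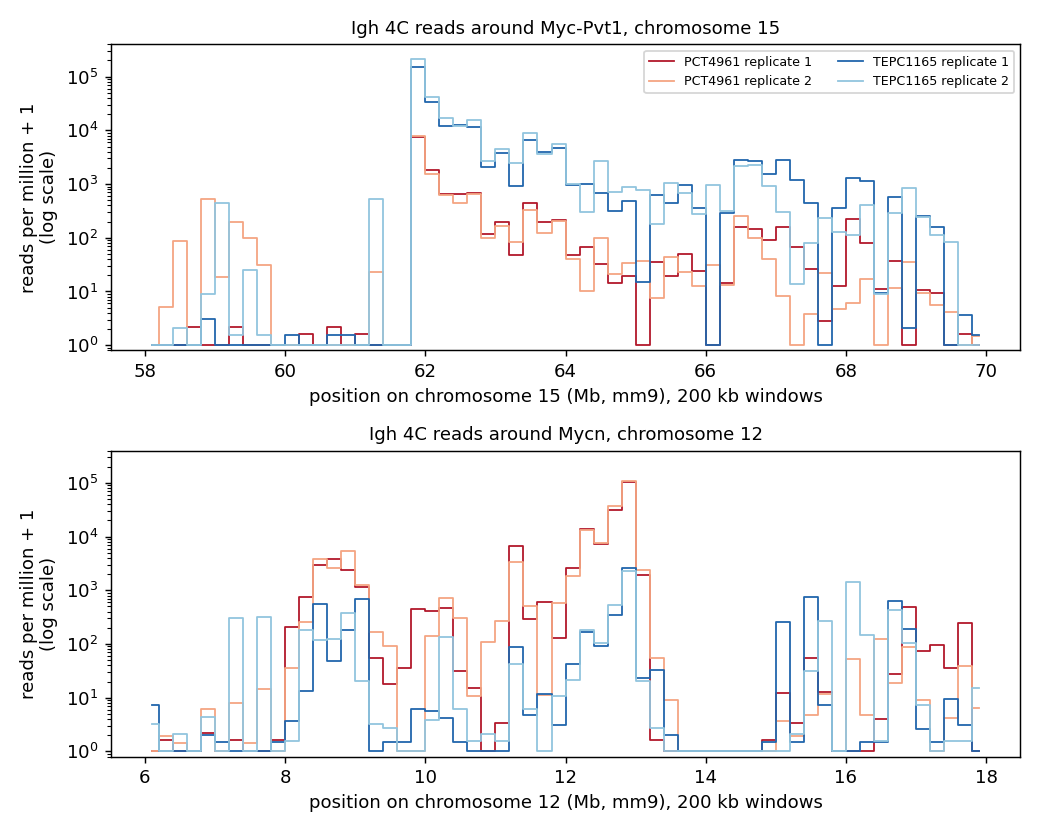
RPM plus 1 (log axis) in 200 kb windows of chromosomes 15 and 12, with 1 line per library. TEPC1165 peaks at 61.8 Mb of chromosome 15 with 282973 and 382973 reads in that window, and PCT4961 at 12.8 Mb of chromosome 12 with 170587 and 237211; each tumor falls off to 1 side.

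Summed over windows, reads of the rest of both chromosomes differed in the same directions, with few windows called: 1 of 207 tested was lower on chromosome 15 and 6 of 348 were higher on chromosome 12. These sums include stretches next to the partner regions, such as 63 to 65 Mb of chromosome 15 and 11 to 12 Mb of chromosome 12. Of the 327793 and 423452 PCT4961 reads of the rest of chromosome 12, 42197 and 64458 lay at 115.6 to 116.2 Mb. The sums therefore do not show a difference spread along each chromosome. The rest of chromosome 15 took 2.79% ± 0.139 of the reads in PCT4961 and 15.9% ± 1.09 in TEPC1165 (SD, n = 2 each; log2 fold change −2.30, SE 0.32, edgeR adjusted p = 1.40e-06 over the list alone). The rest of chromosome 12 took 31.1% ± 0.204 and 12.5% ± 0.296 (log2 fold change 1.53, SE 0.25, edgeR adjusted p = 9.96e-06 over the list alone). With DESeq2 size factors the latter fold change was 0.73. With a library left out it ran from 0.98 to 2.57, and that of the rest of chromosome 15 from −2.88 to −1.30. The median log2 fold change of all tested windows was −1.01, but 0.84 without either TEPC1165 library, 0.031 with no filter and −1.70 with DESeq2 size factors, so values relative to it move with the setting. Relative to −1.01 the Myc-Pvt1 value was −2.82, the Mycn value 7.45, the rest of chromosome 15 −1.29 and the rest of chromosome 12 2.54. The calls of these 4 regions were lost with DESeq2 as the test and without PCT4961 replicate 2, with fold changes of the same sign. On detected fragments in place of reads the Myc-Pvt1 value was −0.22, no longer past the threshold, and the Mycn value 0.39. Detection ignores how many reads a fragment holds, and same-numbered libraries may share reads, so it shows little of a difference in reads. At Myc-Pvt1 212 and 234 fragments were detected in PCT4961 and 235 and 259 in TEPC1165.

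The light chain loci Igk and Igl did not pass the test. Igk, the kappa light chain locus, took 0.493% ± 0.0695 of the reads in PCT4961 and 0.347% ± 0.129 in TEPC1165 (SD, n = 2 each). Its log2 fold change was 0.69 (SE 0.92, edgeR adjusted p = 0.556 over the list alone), turned to −0.073 with DESeq2 size factors, and was 1.63 and past the threshold without TEPC1165 replicate 1. Igl, the lambda light chain locus, took 0.0566% ± 0.0385 and 0.153% ± 0.0859 (log2 fold change −0.96, SE 1.67, edgeR adjusted p = 0.571 over the list alone), and its fold change ran from −1.94 to −0.035 when a library was left out. Single windows of both loci stood out on their chromosomes. The highest PCT4961 window of chromosome 6 was 6:70600001-70800000, inside Igk, with 3542 and 4096 reads against 766 and 936 in TEPC1165, and 13 to 15 fragments detected in each library. The highest TEPC1165 window of chromosome 16 was 16:19000001-19200000, inside Igl, with 1373 and 1380 reads against 149 and 493 in PCT4961. Neither window passed the edgeR test (adjusted p = 0.795 and 0.823), though the Igk window did without TEPC1165 replicate 1, with a log2 fold change of 3.10. The remaining highest windows rested on few fragments. They were 16:95800001-96000000, 1:58200001-58400000 and 17:56600001-56800000 in PCT4961, with at most 5 fragments in a library, and 6:66200001-66400000 in TEPC1165, with 1 fragment and 2255 reads in replicate 1 but 1 read in replicate 2.

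Over the genome, 18 of the 3449 tested windows were called different between the tumors, and they lay on 2 chromosomes. Differences elsewhere are not excluded. On simulated counts with the full estimated spread, the test called 0 of 26 windows changed 64-fold with a mean of at least 1000 reads. The 12 windows higher in PCT4961 were on chromosome 12 and the 6 lower ones on chromosome 15, each with both libraries of a tumor on the same side. The higher windows formed 3 groups. In the group around Mycn, 7 windows between 11.2 and 13.2 Mb had log2 fold changes of up to 7.40. That largest value rested on 2 to 4 of 73 fragments per library, in 12:13000001-13200000. Between 8.6 and 9.0 Mb there were 2 windows, with 5.79 (SE 1.21, edgeR adjusted p = 0.0246) and 4.69 (SE 1.00, edgeR adjusted p = 0.0299). Beyond the bait there were 3, among them 12:115800001-116000000 with 5.91 (SE 0.49, edgeR adjusted p = 7.61e-08) and 12:117600001-117800000 with 6.10 (SE 1.24, edgeR adjusted p = 0.0188). The windows at 8.6, 12 and 13 Mb and 12:117600001-117800000 lost the call without PCT4961 replicate 1, and these and the windows at 8.8 and 115.6 Mb also lost it with a 5 times stricter filter. The 6 lower windows had log2 fold changes from −3.65 to −3.85: 5 adjoined from 61.8 to 62.8 Mb of chromosome 15, and 1 lay at 63.4 Mb. Those at 62.2, 62.4, 62.6 and 63.4 Mb lost the call without TEPC1165 replicate 2, and that at 63.4 Mb also with the stricter filter. The count fell to 0 without PCT4961 replicate 2 (9 windows at unadjusted p under 0.05) and was 41 without TEPC1165 replicate 1 (35 higher and 6 lower in PCT4961). It was 27 without TEPC1165 replicate 2 (25 higher and 2 lower) and 18 without PCT4961 replicate 1 (8 higher and 10 lower). DESeq2 as the test called 0 (165 at unadjusted p under 0.05), as did edgeR on detected fragments in place of reads (7). Detected fragments show little of a difference in reads, so their result says little against the calls.

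By chromosome, chromosome 12 held 57.5% ± 1.16 of the reads outside the bait region in PCT4961 and 12.9% ± 0.296 in TEPC1165, and chromosome 15 held 4.58% ± 0.168 and 45.3% ± 6.26 (SD, n = 2 each). With each read taken as independent, the 95% Wilson interval of the chromosome 12 share of PCT4961 replicate 1 was 56.6% to 56.8%. That library held 149 reads per detected fragment, and reads may be copies, so the interval may be far too narrow. The libraries of the tumors did not overlap in either share (exact permutation p = 0.333, the smallest the design allows; 0.538 adjusted over 21 chromosomes). The mean shares of the other 18 chromosomes without Y ran from 0.839% to 3.38% in PCT4961 and from 1.17% to 3.78% in TEPC1165. The tumors did not overlap for 11 of them, where chance gives 33.3%. Shares of a library are parts of one whole, so the shifts on chromosomes 12 and 15 also move the others, and this count does not test them. Counted as windows with reads in place of reads, the differences were −0.177 percentage points for chromosome 12 and −0.351 for chromosome 15. That count ignores how many reads a window holds.

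Raised contact extended mainly to one side of each tumor's highest window. Whether a rearrangement joins these sequences to the bait, or they contact it without one, was not tested for either tumor. In TEPC1165 it ran from 61.8 to 65.0 Mb of chromosome 15 (3.2 Mb, 16 windows) and held 463357 and 596337 reads. The 1 Mb below 61.8 Mb held 1 and 927 reads. In the GRCm38 gene order Myc is followed, towards higher coordinates, by Pvt1, Gsdmc genes, Cyrib, Asap1, Adcy8 and Efr3a. In PCT4961 it ran from 11 to 13.2 Mb of chromosome 12 (2.2 Mb, 11 windows) and held 279007 and 383615 reads, with 1 and 133 reads in the next 1 Mb. Towards lower coordinates Mycn is followed by Cyria, Rad51ap2, Vsnl1, Smc6, Gen1 and Msgn1 in the GRCm38 gene order. Relative to the highest window, PCT4961 kept 17.5% ± 0.435 at 0.2 to 0.8 Mb on the Mycn side, and TEPC1165 kept 11.96% ± 1.43 on the Myc side. At 0.8 to 2.0 Mb the values were 1.33% ± 0.473 and 3.09% ± 0.199, and at 2.0 to 5.0 Mb 0.868% ± 0.0561 and 0.669% ± 0.0833 (SD, n = 2 each). Around 15:61800001-62000000, the highest PCT4961 window outside chromosome 12, the PCT4961 run had length 0 because TEPC1165 was higher there. The lengths depended on the rule: without PCT4961 replicate 1 the PCT4961 run was 3.6 Mb, without TEPC1165 replicate 1 the TEPC1165 run was 5.4 Mb, and in bins of 1 Mb they were 6 and 11 Mb. With a 2-fold rule the PCT4961 run was 1.4 Mb, and with 1 window below allowed the TEPC1165 run was 7.6 Mb.

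Around the bait, PCT4961 had more contact than TEPC1165 on the side of higher coordinates. There PCT4961 had 27723 ± 193 RPM per window within 1 Mb against 1663 ± 134 in TEPC1165 (SD, n = 2 each), a ratio of 16.7. The ratio was 18.3 at 1 to 2 Mb, 12.03 at 2 to 5 Mb and 7.29 at 5 to 10 Mb, and the tumors did not overlap in any of these bands. Chance gives 33.3% for this per band, and on the side of lower coordinates only the band at 1 to 2 Mb overlapped. At 2 to 5 Mb TEPC1165 had 67.1 RPM per window on the higher side and 860 on the lower side, and PCT4961 807 and 1095. At 1 to 2 Mb TEPC1165 had 306 and 2111, and PCT4961 5596 and 2189. The ratios thus reflect few reads of TEPC1165 on the higher side as well as many of PCT4961 within 2 Mb. With the median window in place of the mean the 4 ratios on the side of higher coordinates were 1.27, 5.72, 6.62 and 25.7. The mean within 1 Mb rested on the window next to the bait, 12:114600001-114800000, with 184285 and 238290 reads against 10313 and 11283. At 5 to 10 Mb the ratio of means was 36.6 without TEPC1165 replicate 1 and 4.05 without TEPC1165 replicate 2. On the side of lower coordinates the ratio within 1 Mb was 1.24 over the 4 windows beside the bait window and 2.90 with the bait window included. It was 1.04 at 1 to 2 Mb, 1.27 at 2 to 5 Mb, 2.12 at 5 to 10 Mb and 1.19 at 10 to 20 Mb. By the median, the last 3 became 0.406, 0.453 and 0.627. Beyond 50 Mb, where Mycn lies, it was 7.95 by the mean and 1.31 by the median. The medians there overlapped and lay under the floor of 3 counts, at 0.599 and 0.459 RPM in PCT4961 and 0.529 and 0.281 in TEPC1165. The highest TEPC1165 window of chromosome 12 outside the bait region, 12:113000001-113200000, had 6237 and 6328 reads against 7620 and 7166 in PCT4961 (log2 fold change 0.85, SE 0.69, edgeR adjusted p = 0.795). It passed the threshold without TEPC1165 replicate 1, with 1.32.

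**Figure D2:**
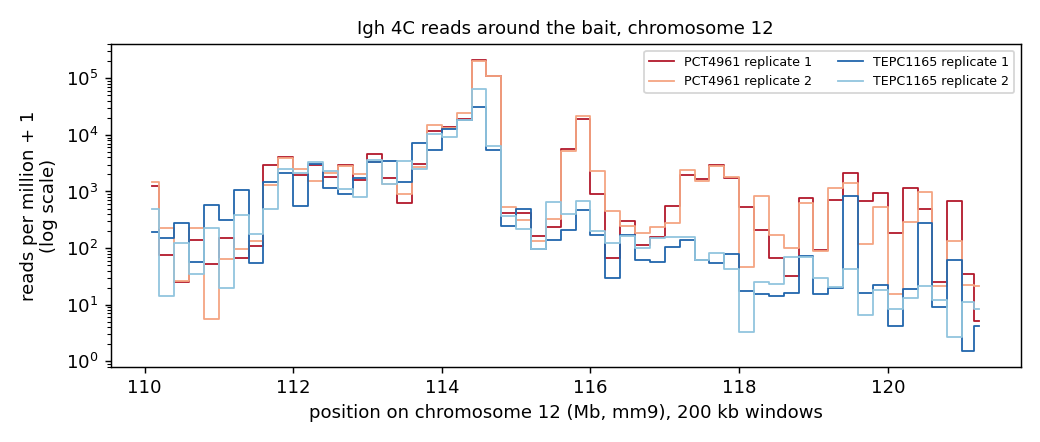
RPM plus 1 (log axis) in 200 kb windows of chromosome 12 from 110 Mb to the end, with 1 line per library. PCT4961 lies above TEPC1165 from 115.6 to 116.2 Mb, with 42197 and 64458 reads against 1624 and 2257, and the libraries lie close together from 114.8 to 115.6 Mb.

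Replicates agreed closely in the windows with most reads and poorly elsewhere. Across all windows the Pearson correlation of reads was 0.997 between the PCT4961 libraries and 0.985 between the TEPC1165 libraries, and 0.218 to 0.276 between tumors. On the log2 scale, where low windows count as much, the replicates reached 0.38 and 0.28, and libraries of different tumors with the same number 0.69 and 0.68. Outside chromosomes 12 and 15 the replicates reached 0.25 in PCT4961 and 0.12 in TEPC1165, and same-numbered libraries 0.65 and 0.64.

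**Figure D3:**
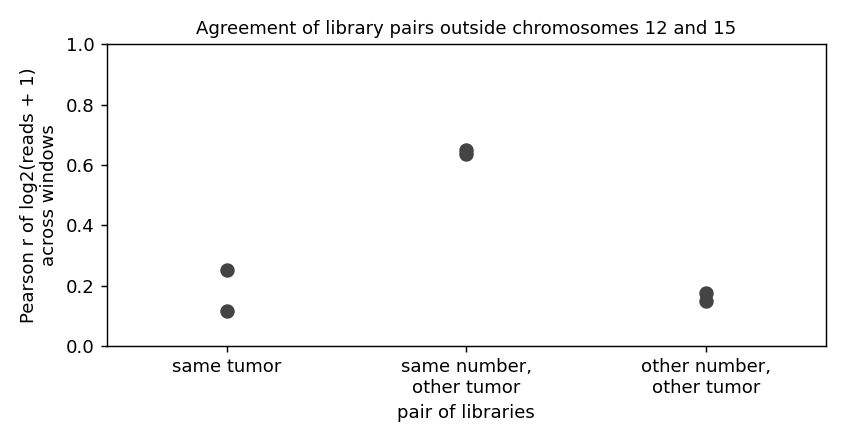
Pearson correlation of log2(reads + 1) across 11743 windows outside chromosomes 12 and 15, with 1 point per pair of libraries. Same-numbered libraries of different tumors reach 0.65 and 0.64, above the replicates of a tumor at 0.25 and 0.12.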

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

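Detected fragments, reads corrected for sharing, bins of 1 Mb, the TEPC1165 run, and decay without a library or the bait window were chosen after the data were seen. Of the 18 called windows (12 higher, 6 lower in PCT4961), all tested under any alternative kept their direction, and 176 of 258 repeats kept the call. The repeats with other prior counts change only the fold change and could not lose the call, so this share is too favourable. The count was 0 with DESeq2 as the test, 0 with detected fragments, 11 with a 5 times stricter filter (6 higher), 2 among windows outside chromosome 12 (0 higher, 2 lower), and 31 with reads corrected for sharing (20 lower). Scaling by total reads gave 18 higher and 9 lower, DESeq2 size factors 10 and 11, no filter 10 lower, and bins of 1 Mb 6 higher. Leaving out a library gave 0 to 41 windows (0 to 35 higher, 0 to 10 lower); the lone library was assumed to vary like the others. With a replicate block 12 were called, 7 of them higher; the windows at 8.6, 8.8, 12, 13 and 117.6 Mb of chromosome 12 and 63.4 Mb of chromosome 15 were not among them. Same-numbered libraries deviated together (r = 0.68 over 3449 windows), but the labels do not say that a number pairs libraries, so this is a hint from the data. With the block the log2 fold changes of the fixed regions kept their side of the threshold.

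Under DESeq2 the calls of Myc-Pvt1 (−4.62), Mycn (5.62), the rest of chromosome 15 (−3.09) and the rest of chromosome 12 (0.73) were lost, and Igk turned to −0.073. With DESeq2 size factors Igk was −0.073. Detected fragments, which show little of a difference in reads, ended the call of Myc-Pvt1 (−0.22). Reads corrected for sharing gave 8.42 for Mycn; at Myc-Pvt1 the correction exceeded the PCT4961 reads and no fold is given. Leaving out a library gave −4.37 to −2.47 for Myc-Pvt1, 5.93 to 7.49 for Mycn, 0.024 to 1.63 for Igk, −1.94 to −0.035 for Igl, −2.88 to −1.30 for the rest of chromosome 15, 0.98 to 2.57 for the rest of chromosome 12. The causes were not tested, beyond the fewer windows or libraries in a fit. The chromosome 12 difference was 40.9 percentage points with 10 Mb on each side of the bait left out; by windows with reads it reversed to −0.177, and chromosome 15 moved to −0.351. The PCT4961 run was 1.4 Mb with a 2-fold rule, 6.0 in bins of 1 Mb and 2.2 to 3.6 without a library; the TEPC1165 run was 7.6 with 1 window below allowed, 11 in bins of 1 Mb and 3.2 to 5.4 without a library. By the median, log2 ratios on the lower side of the bait reversed at 2 to 5 (−1.30), 5 to 10 (−1.14) and 10 to 20 Mb (−0.67); without a library the log2 ratio at 1 to 2 Mb ran from −0.026 to 0.13. Of the 7 named windows that were not called, 6:66200001-66400000 ranged from −6.14 to 4.98 without a library and 17:56600001-56800000 was −0.041 with detected fragments. Bins of 100 and 500 kb could not be made from 200 kb windows and were not run, and gene groups were void. Of the windows with reads, 62.7% to 66.1% held 1 detected fragment, at 149 to 204 reads per detected fragment in a library, so few fragments stand behind most windows.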

Other observations

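The stretches in this part were chosen after the data were seen, and so were all tests below. In PCT4961 a further stretch of chromosome 12, from 8.4 to 9.2 Mb, held 17153 and 28330 reads against 2806 and 1134 in TEPC1165, apart from the run around Mycn in 200 kb windows but within it in bins of 1 Mb, where the run spans 8 to 14 Mb. The end of the chromosome, from 117.2 Mb on, held 28269 and 32926 reads in PCT4961 and 3240 and 1256 in TEPC1165. The bait window and the next one held 537696 and 685369 reads in PCT4961 and 68912 and 125951 in TEPC1165.

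Windows outside chromosomes 12 and 15 were shared by libraries of the same number rather than by libraries of the same tumor. Of the windows with at least 300 reads in a library, at least 99.5% also held reads in the same-numbered library of the other tumor, which is consistent with reads passed between same-numbered libraries. At most 57.3% were seen in the other-numbered library of the other tumor, which argues against fragments that map or amplify in every library. Replicates of a tumor reached a correlation of at most 0.25 there, below the 0.64 of the lower same-numbered pair, which argues against contacts common to the 2 tumors. At which step reads might pass was not tested.

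The reads of each tumor at the partner region of the other may have passed from the other tumor's library. At Myc-Pvt1 the PCT4961 reads were at most 4.53% of the TEPC1165 reads, and outside chromosomes 12 and 15 the same percentage had quartiles of 4.18% to 6.12% for number 1 and 4.16% to 7.03% for number 2. Contact in PCT4961 itself as the main source would lift the percentage above those quartiles, and the lower value, 4.46%, lay under the medians of 4.95% and 4.98%, so at most a small contact of its own stays open. At Mycn the TEPC1165 reads were at most 2.34% of the PCT4961 reads, inside the quartiles of 1.20% to 6.53% and 1.02% to 3.54% in the other direction. There contact in TEPC1165 itself cannot be told apart from passed reads, since the lower value, 1.51%, lay inside wide quartiles but above its median of 1.48%.

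The stretch of chromosome 12 from 115.6 to 116.2 Mb, beyond the bait, was raised in PCT4961 relative to TEPC1165. PCT4961 held at least 25.98 times the reads of TEPC1165, more than reads passed from TEPC1165 would give. The lower PCT4961 library held 18.7 times the reads of the higher TEPC1165 library, so the raised reads were not those of 1 library alone. The stretch was chosen for its higher reads in PCT4961, so neither check could have failed and neither counts as a test. A rearrangement that joins this stretch to the bait could leave the windows between them little raised, and there the ratio of reads was at most 1.195 and that of read shares outside the bait region 1.88 and 1.37, against 43.0 and 32.8 in the raised stretch. As many fragments were detected there in PCT4961 (110 and 110) as in TEPC1165 (106 and 108). Reads shared between same-numbered libraries could fill in fragments, so this count cannot show whether sequence was lost. A rearrangement and a folded contact without one cannot be told apart. The tumor itself, with 1 tumor per group, stays an open biological explanation.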
